A study of Mus musculus with 6 samples.

How the data were processed

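Liver nuclei of 3 SBR and 3 sham samples were measured by single-nucleus RNA sequencing. Per the labels' protocols, nuclei were released from frozen lobes, stained with NucBlue, sorted by flow cytometry and made into 3' libraries with 10x Genomics v3.1 chemistry. The deposited files were 18, with 3 per sample: a list of barcodes, a list of 32285 genes (identifier and symbol) and a matrix of UMI counts per gene and nucleus. Per the file headers, the matrices of counts were written by Cell Ranger 7.2.0, and the values were whole numbers that no step had normalized. The submitters' processing notes also name DRAGEN, STAR, Subread, featureCounts and Salmon, with no role. The genome build and annotation were not given in the sources used here. Coordinates were therefore looked up by gene identifier in GENCODE vM21 on GRCm38, which was not taken as the build of the counts. The deposited barcodes were a called subset, since the lowest total per barcode was 500 to 505 UMIs.

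Groups were taken from the sample labels. Replicate numbers were given in accession order and pair no samples, and the labels give no batch. No pair of libraries was a duplicate: counts of every pair differed by far more than sampling noise (lowest chi-square per degree of freedom 126). Nuclei with at least 500 genes and at most 5% mitochondrial UMIs were kept. Below 500 genes lay 109, 89 and 124 sham and 145, 1867 and 120 SBR barcodes, and 43, 23, 44, 59, 135 and 33 failed the mitochondrial limit. Doublets were scored in each sample by the share of simulated sums of nuclei among the nearest neighbours, as Scrublet does but in code written here, and the highest scores were left out at a rate of 0.8% per 1000 barcodes with at least 200 genes, which removed 10.45%, 13.27% and 14.64% of sham and 12.4%, 9.66% and 7.77% of SBR nuclei. Kept were 11567, 14291 and 15479 sham and 13398, 9107 and 8821 SBR nuclei, with 115996269, 140988767, 124101257, 77979887, 23166659 and 52812654 UMIs. Their median mitochondrial share was 0.033%, 0.038% and 0.025% in sham and 0.059%, 0.082% and 0.066% in SBR.

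Counts were scaled to 10000 per nucleus, logged, limited to 2000 variable genes with values clipped at 10, reduced to 30 principal components and joined by 20 nearest neighbours. Leiden clustering (leidenalg 0.10.2, igraph 0.11.9) ran at resolution 1. Clusters were named with the suffix -like from marker lists of 10 cell types fixed before the data were examined. A cluster of at least 20 nuclei took the name of a class other than hepatocytes when that class's markers reached a mean log2 fold of 1.5 over all other nuclei, the next class stayed within a share of 0.8 of it and at least 3 markers were detected in 5% of the nuclei. Hepatocyte-like clusters, named after these, needed at least 3 hepatocyte markers at 1.5-fold over the other named clusters of the same libraries. Clusters whose 10 leading genes held more markers of another class, or with few UMIs and no own marker there, stayed unnamed. The naming thresholds were set after the clusters had been seen, and this rule was the last of 3 tried, lowered so that cluster 13 was named. By mean fold of the markers, the first rule, clusters 5, 9, 13 and 20 were left out and hepatocyte-like nuclei made up 72.12%, 74.05% and 75.14% of sham and 32.27%, 5.03% and 18.09% of SBR nuclei. With 3 markers at 2-fold, the second, cluster 13 was left out, and the shares were 72.21%, 74.38% and 75.25% and 51.98%, 55.3% and 31.73%. Under the rule used they were 72.21%, 74.41% and 75.26% and 60.34%, 62.17% and 43.33%. Unnamed nuclei made up 2.87%, 3.39% and 2.27% of sham and 2.4%, 2.49% and 3.84% of SBR nuclei. Cluster 13 nuclei had 1.68 times the median UMIs of their libraries, and with doublets kept a cluster like it was unnamed. Of the other hepatocyte-like clusters made up mostly of SBR nuclei, 4, 9 and 20 had 1.58, 1.77 and 1.57 times and 5 had 1.105 times. This depth therefore did not set cluster 13 apart.

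Raw counts were summed per sample and class, and classes with at least 20 nuclei in every sample were tested with edgeR 4.0.16 in R 4.3.3 (TMM, filterByExpr, robust quasi-likelihood fit, Benjamini-Hochberg adjustment at 0.05). No covariate was used. Named in hepatocyte-like nuclei were the 12 higher and 12 lower genes with the largest change among those that passed, averaged at least 10 CPM and did not overlap between the groups, up to 4 members per list with the lowest p, and Cyp7a1, Tlr4, Col1a1 and Cdkn1a. In other classes 5 higher and 5 lower genes above their hepatocyte-like level were named, and for the lobule interaction the 5 with the lowest p. Symbols of unnamed gene models were passed over, and the results of some genes that met the rule are not reported here. Members named because they went against their list, Npas2 and Col1a1 in other classes and the leading genes of clusters were chosen after their values had been seen. The 25 gene lists and the marker lists were tested with camera of limma 3.58.1 at a preset correlation of 0.01, and again with an estimated one. Only list members that passed the count filter were tested and counted. A member near silent in 1 group thus entered only by being higher in the other. Over the 34 lists of hepatocyte-like nuclei 19 passed with the preset and 0 with the estimated correlation, and 21 passed by fry, which tests whether members move one way and does not compare them with other genes. In the other classes 66 of 176 list tests passed with the preset and 5 with the estimated correlation. A fold against 0 counts used a floor of 3 counts over the group, and ratios with 1 to 3 counts have exact 95% binomial intervals.

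Shares and depth were compared by two-sided exact permutation over the 10 splits of 6 samples (scipy 1.17.1), with Benjamini-Hochberg adjustment over classes. Hepatocyte-like nuclei were clustered again at resolution 0.5. For the lobule comparison, each sample's hepatocyte-like nuclei were ranked by the mean log value of the periportal less that of the pericentral list, the ranks were split into 3 equal parts, of which the outer 2 were summed, and the zone by surgery term was tested with sample as a block and the 56 genes of both lists left out. The other-cell RNA share of hepatocyte-like sums was estimated as the share of other classes' markers in them, divided by that in the summed other classes of the same library.

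Tests were run on simulated data with known changes drawn from the samples' own means, dispersions and library sizes. Of genes changed 2-fold and 8-fold, edgeR recovered 42% and 88% over 16843 genes for hepatocyte-like, 56% and 98% over 11958 for endothelial-like, 58% and 96% over 11681 for mesenchymal-like, 38% and 98% over 10604 for macrophage-like, 52% and 90% over 4791 for T and NK-like, 34% and 88% over 4740 for cholangiocyte-like and 52% and 86% over 5906 for other myeloid-like nuclei, and 68% and 94% over 15220 for the interaction. Over these 8 comparisons 89 of 1049 calls were false, 8.5%, above the nominal 5%, with 16 of 119 for hepatocyte-like nuclei by edgeR and 46 of 157 by DESeq2. Only 50 genes were changed at each fold, a small part of the genes run, so the false share among the real calls may differ. Alternatives, given in the closing section, were DESeq2 1.42.0, other size factors, no count filter, each sample left out, doublets kept, stricter or looser filters, thinned or equal numbers of nuclei, a fold threshold of 1.2, marker assignment and a covariate of other cells' markers. Python 3.11.15, numpy 2.4.6, pandas 2.3.3 and matplotlib 3.10.9 were used.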

Results

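Single nuclei were sequenced from the livers of male mice 2 weeks after small bowel resection (SBR), in which 75% of the small bowel was taken from its proximal end, or after a sham operation, in which the bowel was cut and rejoined. Each group held 3 samples. Mice were 8 weeks old, ate a liquid diet, and the left anterior lobe was used. The labels do not state that the samples came from separate mice, so p-values measure only the spread between these samples, which may be technical. The deposited matrices held 13069, 16590 and 18302 barcodes in sham replicates 1, 2 and 3, with 140887277, 177154369 and 166451743 UMIs. In SBR replicates 1, 2 and 3 they held 15498, 12083 and 9717 barcodes, with 97098498, 29265520 and 61984630 UMIs. After filtering, 72663 nuclei remained and formed 34 clusters.

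Fewer UMIs were counted per nucleus in SBR than in sham, a measure that also depends on sequencing and capture. The median per nucleus was 8177 UMIs ± 1010 (SD, n = 3 samples) in sham and 3626 ± 1430 (SD, n = 3) in SBR, and the median number of genes was 3161 ± 183 against 1717 ± 642. Every SBR sample lay below every sham sample for both measures (two-sided exact permutation p = 0.1, the smallest that 3 samples against 3 can give). SBR replicate 2 was the shallowest, with a median of 2031 UMIs. Among hepatocyte-like nuclei alone the medians were 11419, 10832 and 8491 UMIs in sham and 6886, 2649 and 8523 in SBR.

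**Figure D1:**
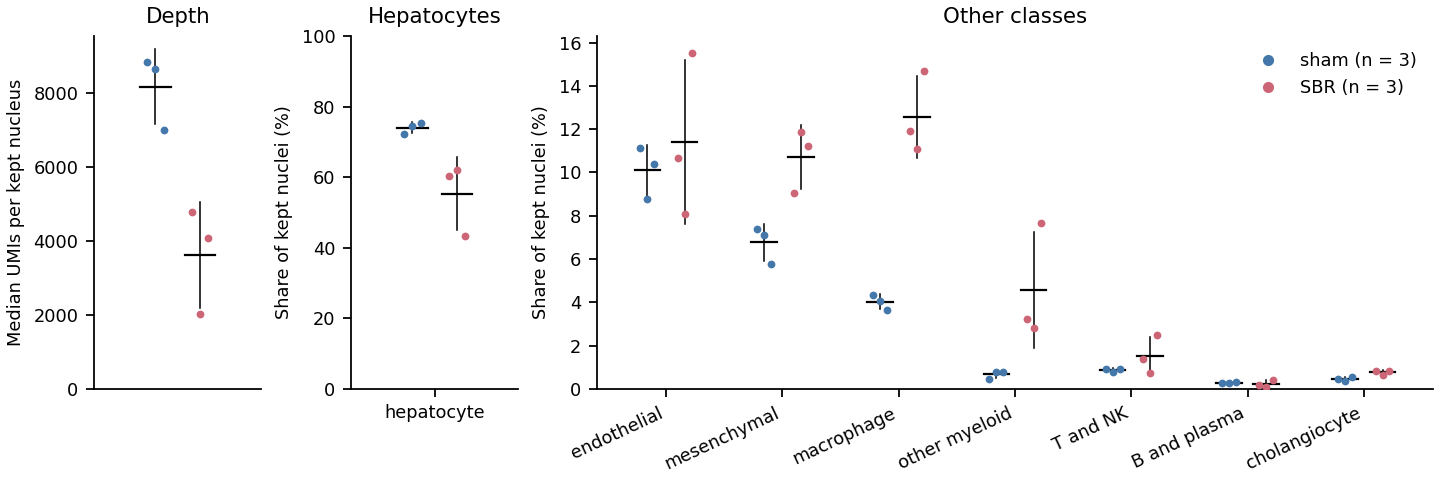
Median UMIs per nucleus and the percent of nuclei in each cell class, 1 point per sample, with the group mean and SD. Sham samples lay between 7013 and 8851 UMIs and SBR samples between 2031 and 4776, and macrophage-like nuclei made up 3.66 to 4.35% of sham and 11.1 to 14.68% of SBR nuclei.

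The first comparison asked which cell types the resected animals' livers held. Macrophage-like nuclei, the resident and recruited phagocytes, made up 12.56% ± 1.88 (SD, n = 3) of SBR nuclei against 4.016% ± 0.343 (SD, n = 3) in sham. Other myeloid-like nuclei, cluster 15 led by Gpr141, Mctp1 and Wdfy4 and cluster 26 led by Siglech, Bcl11a and Runx2, made up 4.577% ± 2.68 against 0.6808% ± 0.2. Cluster 23, led by Csf3r and S100a9, stayed unnamed and is not counted there. Mesenchymal-like nuclei, which include the vitamin A-storing stellate cells, made up 10.7% ± 1.48 against 6.773% ± 0.86, and cholangiocyte-like nuclei, the lining of bile ducts, 0.7766% ± 0.102 against 0.4606% ± 0.103. Hepatocyte-like nuclei made up 55.28% ± 10.4 in SBR and 73.96% ± 1.57 in sham.

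These 5 classes did not overlap between the groups (two-sided exact permutation p = 0.1 for each, adjusted p = 0.18 by Benjamini-Hochberg), so no share passed 0.05 in a test that cannot go below 0.1, and chance alone separates 3 samples from 3 in 10% of cases. With edgeR's quasi-likelihood test on nuclei per class, the log2 ratio was 1.65 for macrophage-like (adjusted p = 4.96e-05), 2.74 for other myeloid-like (8.13e-05), 0.66 for mesenchymal-like (0.0304) and -0.42 for hepatocyte-like nuclei (0.044), while cholangiocyte-like nuclei (0.75, adjusted p = 0.106) did not pass. Endothelial-like nuclei made up 10.1% ± 1.19 in sham and 11.42% ± 3.79 in SBR (exact permutation p = 0.8), T and NK-like nuclei 0.8755% ± 0.0758 and 1.529% ± 0.877 (p = 0.4), and B and plasma-like nuclei 0.2892% ± 0.0364 and 0.2387% ± 0.172 (p = 0.7). A lower hepatocyte-like share by itself raises the shares of the other classes. In a comparison chosen after the results were seen, mesenchymal-like nuclei made up 24.64% of SBR and 25.96% of sham nuclei outside the hepatocyte class (exact permutation p = 0.7). Cholangiocyte-like nuclei made up 1.776% and 1.779%, so the mean of neither class was larger in SBR there. Nuclei had been sorted on a DNA stain, and depth differed between the groups. With at least 1000 genes and at most 1% mitochondrial UMIs per nucleus only the macrophage-like and other myeloid-like shares stayed without overlap, the difference in hepatocyte-like share went from -18.68 to -7.28 percentage points, and that in mesenchymal-like share from 3.931 to 0.2445. With doublets kept the hepatocyte-like difference was -30.43 points, by marker assignment -11.35, and under the first and second naming rules -55.31 and -27.61. Leaving out SBR replicate 3, the difference was 2.354 points for other myeloid-like nuclei, against 3.897 with it. Assigning nuclei by markers alone, the other myeloid-like difference was 0.1531 points (exact permutation p = 0.2).

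Hepatocyte-like nuclei of the groups fell into different clusters, and some clusters came mostly from 1 sample. Clusters 3 and 7 drew 6273 of 6370 and 3871 of 3909 nuclei from sham replicate 3. Cluster 5, led by Gm19951, Gm42418 and Gm48099, drew 3738 of 4044 from SBR replicate 2. Without cluster 5 all 136 named hepatocyte results that could be compared kept direction and call. Clusters 1, 2, 3, 7, 12, 17 and 25 held 99.73% of sham and 0.47% of SBR hepatocyte-like nuclei, and clusters 4, 5, 9, 13 and 20 held 0.27% and 99.53%. Cluster 13, led by Slc24a3, Creb5 and Nrg1, was named hepatocyte-like from Apob, Hnf4a, Abcb11 and Ahsg, of which 2 reached 2-fold. Its hepatocyte markers had a mean log2 fold of 0.08 over the named clusters of other classes. Its cholangiocyte markers had one of 0.13 over all other nuclei. These references differ, so the values cannot be compared, and the identity of cluster 13 stays open. It counted 0, 5 and 1 nuclei in the sham samples and 1121, 626 and 1023 in the SBR samples. Hepatocyte-like nuclei were clustered again with 8551 of the 8552 genes at an unadjusted p below 0.05 left out (the other rounded to 0.05), on 2000 variable genes among the rest.

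That clustering gave 13 sub-clusters. Sub-cluster 10, led by Themis, Gdf15, Osmr and Mospd1, made up 14.08% ± 11.7 (SD, n = 3) of SBR and 0.04474% ± 0.0674 (SD, n = 3) of sham hepatocyte-like nuclei, and cluster 13 supplied 79.5% of its 2423 nuclei. It made up 18.24% and 23.08% in SBR replicates 1 and 3 but 0.92% in SBR replicate 2. Sub-cluster 11, led by the cell division genes Anln, Nusap1 and Cenpa, made up 2.057% ± 1.08 against 0.1289% ± 0.134. Sub-cluster 12, led by the interferon-induced genes Ifit1, Cmpk2 and Cxcl10, made up 0.3209% in SBR and 0.6593% in sham (exact permutation p = 0.3). Sub-clusters 2, 4, 9, 10, 11 and 13 did not overlap between the groups (two-sided exact permutation p = 0.1, adjusted p = 0.2167). Sub-clusters 1 to 9 came almost wholly from 1 sample each (93.8 to 99.9%). Numbers 2, 4 and 9 came from an SBR sample and the others from a sham sample, so sham samples also parted from each other, and without sham replicate 3, 10 sub-clusters were without overlap in place of 6.

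The second comparison asked how hepatocytes differed after resection. By camera with a preset correlation, lists of male-biased genes and of glucose handling, amino acid catabolism and bile acid synthesis were lower in SBR hepatocyte-like nuclei, and lists of oxidative stress, cell division and hepatocyte injury genes were higher. With an estimated correlation none of these lists passed (adjusted p of 0.391 to 0.433 by camera). Of 17100 genes tested, 3120 were higher and 3762 lower in SBR (edgeR's quasi-likelihood test, Benjamini-Hochberg adjusted p of at most 0.05), and 6786 of those 6882 did not overlap between the groups. In all, 9509 genes (55.6%) did not overlap, where chance gives 10%. The samples' summed counts ran from 17631947 to 128183836 UMIs. With nuclei thinned to 1000 UMIs 4371 genes passed, under the first naming rule tried 4406, and with the share of other cells' markers as a covariate 5. Those markers took 0.0376 to 0.0421% of hepatocyte-like UMIs in sham and 0.0658 to 0.0708% in SBR.

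Among the largest increases were Gstm3, a glutathione S-transferase, Cyp2b9, a female-typical cytochrome P450, Abcc4, an efflux pump of the basolateral membrane, Anxa2, a calcium-dependent membrane protein, and Nrg1, a growth factor of the epidermal growth factor family. Gstm3 (ENSMUSG00000004038, chromosome 3, 107963696 to 107969283 on GRCm38) went from 0.122 CPM ± 0.0578 to 35.3 ± 21.3 (SD, n = 3 each), a log2 fold change of 8.14 with a standard error of 0.57 (edgeR adjusted p = 0.000116). Cyp2b9 (ENSMUSG00000040660, chromosome 7, 26173411 to 26210661) went from 0.447 CPM ± 0.356 to 57.7 ± 6.30 (log2 7.04, SE 0.65, edgeR adjusted p = 0.000403). Abcc4 rose by 6.15 on the log2 scale, Anxa2 by 6.47, Arhgef2 by 6.46, Stx3 by 5.13, Elovl7 by 6.66, Creb5 by 7.29, Slc24a3 by 6.41 and Nrg1 by 5.62. Without cluster 13 these 8 values were 5.19, 5.10, 5.85, 3.63, 5.28, 4.86, 3.99 and 4.57 in the same order. Lhfpl2 rose by 5.33, with a value of 2.04 without cluster 13 and of 0.76 under the first naming rule (edgeR adjusted p = 0.145).

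The largest decreases were in the major urinary proteins, pheromone carriers made by male liver. Mup17 (ENSMUSG00000096688, chromosome 4, 61591929 to 61595871 on GRCm38) went from 75.8 CPM ± 12.3 (SD, n = 3) and 27481 counts in sham to 0 counts in SBR, at least 3160-fold lower against a floor of 3 counts over the group. Mup11 had 61890 and 2 counts, a ratio of 10700 (95% counting interval 2950 to 88000), and Mup7 29605 and 3, a ratio of 3400 (1160 to 16500). Mup14 had 15994 and 2 counts (ratio 2750, 762 to 22700) and Mup9 21197 and 3 (ratio 2430, 833 to 11800). These intervals cover counting error only. Mup10 and Mup22 were at log2 -10.40 and -9.29. The Mup genes are near-identical copies of one another, so counts of single members are uncertain. The same limit holds for Serpina1e (log2 -7.34), a member of another family of close copies. Elovl3, a male-typical fatty acid elongase (ENSMUSG00000038754, chromosome 19, 46131897 to 46135694), went from 28.1 to 0.108 CPM (log2 -8.19, SE 0.54, edgeR adjusted p = 9.95e-05). The sulfotransferase Sult2a8 went from 947 CPM ± 239 to 9.51 ± 4.56 (log2 -6.66), and carbonic anhydrase Car3 fell by 6.13 on the log2 scale. Saa2, an acute phase apolipoprotein, had a log2 fold change of -6.26 (edgeR adjusted p = 0.0132), and of -5.92 without SBR replicate 3 (0.0544).

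**Figure D2:**
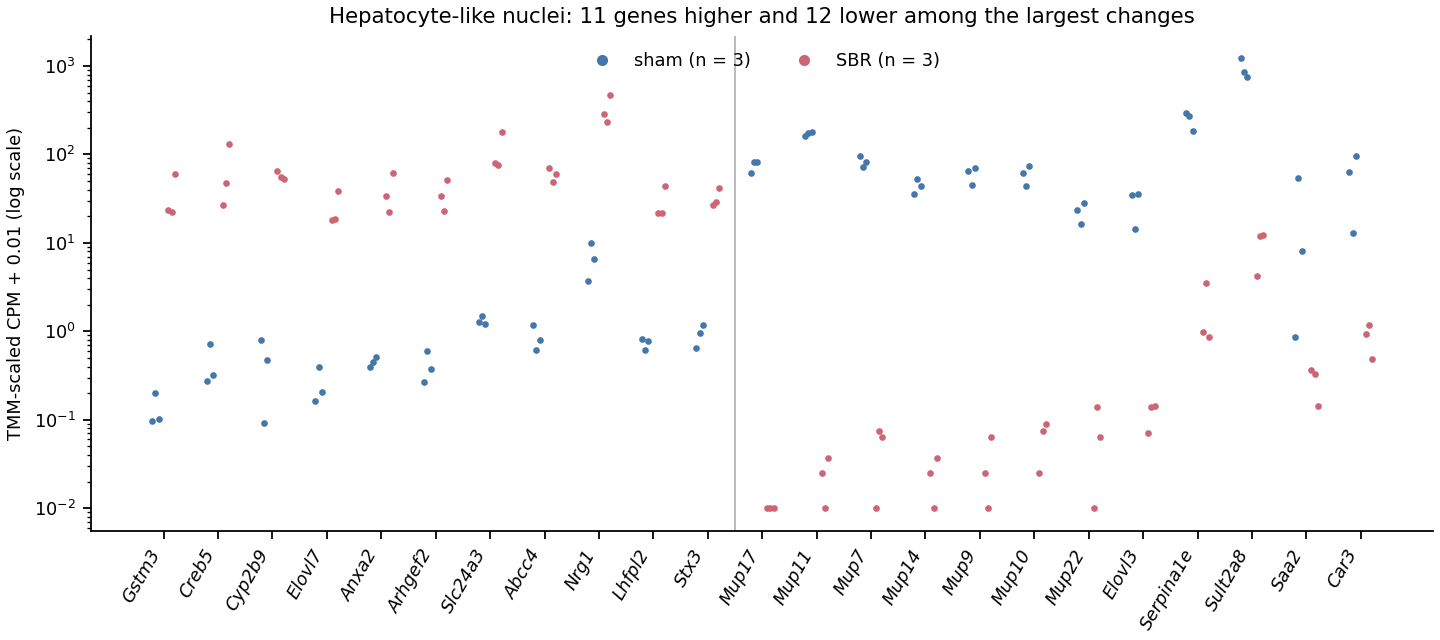
CPM in hepatocyte-like nuclei of 11 genes among those with the largest increase and the 12 with the largest decrease, 1 point per sample, on a log axis after adding 0.01 CPM. The 23 genes were chosen among those whose points did not overlap between the groups, and Mup17 had 0 counts in all 3 SBR samples.

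Genes that differ between male and female liver moved toward the female pattern. Of 26 male-biased genes 23 fell, 1 rose and 2 did not pass (the same adjusted over the list alone), with a median log2 fold change of -3.72 (camera adjusted p = 9.72e-10, and adjusted p = 0.391 with an estimated correlation). Slco1a1, an organic anion carrier, went from 396 CPM ± 63.4 to 8.75 ± 1.28 (SD, n = 3 each), the complement gene C6 had a log2 fold change of -3.66 and the fatty acid hydroxylase Cyp4a12a of -5.74, and Gstp1 rose by 0.86. Of 15 female-biased genes with enough counts to be tested 9 rose, 1 fell and 5 did not pass, also adjusted over the list alone, with a median of 1.85 (camera adjusted p = 0.000118, and adjusted p = 0.433 with an estimated correlation). Other members of this list were too low to be tested. Members near silent in sham entered only by rising, which favours increases in this count. Cyp2a4, a steroid hydroxylase, went from 6 to 1343 counts (log2 9.52) and Prom1 rose by 3.16, while Cyp17a1 fell by 1.14. Slc22a27 rose by 4.32, with a value of 1.59 under the first naming rule (edgeR adjusted p = 0.0964). The 2 lists were written as liver genes of known sex bias, and all mice were male.

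Bile acid synthesis genes were lower. Of 16 bile acid synthesis genes 10 fell, none rose and 6 did not pass (12 fell adjusted over the list alone), with a median log2 fold change of -0.80 (camera adjusted p = 0.00338, and adjusted p = 0.391 with an estimated correlation). Cyp8b1, which makes cholic acid, went from 24.8 CPM ± 7.94 to 1.93 ± 0.811 (SD, n = 3 each), the bile acid ligase Slc27a5 fell by 1.26 on the log2 scale and Cyp27a1, of the alternative pathway, by 0.95. Cyp7a1 (ENSMUSG00000028240, chromosome 4, 6265612 to 6275633 on GRCm38), the rate-limiting enzyme, had 194 CPM ± 124 in sham and 61.1 ± 32.7 in SBR (log2 -1.67, SE 0.56, edgeR adjusted p = 0.0456). Its samples overlapped, and its adjusted p was 0.0622 to 0.156 without sham replicate 1 or 2 or any SBR replicate, at log2 values of -1.05 to -1.98. Of 17 transporters of bile acids and organic anions 5 rose, 7 fell and 5 did not pass, also adjusted over the list alone (median log2 0.04, mean -0.03, camera direction down, adjusted p = 0.762, and adjusted p = 0.868 with an estimated correlation). The uptake carrier Slc10a1 went from 206 CPM ± 28.1 to 55.3 ± 11.0, and the basolateral carrier Slco1a4 rose by 2.67.

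Genes of fatty acid and triglyceride synthesis were lower, and the 3 other lipid lists did not pass by camera. Of 23 genes of fatty acid and triglyceride synthesis 10 fell, 1 rose (Lpin2) and 12 did not pass (11 fell and 1 rose adjusted over the list alone), with a median log2 fold change of -0.56 (camera adjusted p = 0.023, 0.0586 without SBR replicate 2, 0.0868 without cluster 13, and adjusted p = 0.391 with an estimated correlation). The lipogenic regulator Thrsp fell by 3.89, fatty acid synthase Fasn by 1.73, ATP citrate lyase Acly by 1.85 and the last enzyme of triglyceride assembly, Dgat2, by 0.81. Of 26 genes of fatty acid oxidation 9 rose, 3 fell and 14 did not pass, also adjusted over the list alone (median 0.47, camera adjusted p = 0.0653, and adjusted p = 0.607 with an estimated correlation), and the camera value was 0.0291, 0.0492 and 0.0322 without sham replicate 1, sham replicate 3 or SBR replicate 2, and 0.0077 without cluster 13. The acyl-CoA thioesterase Acot2 rose by 4.00 and the fasting hormone Fgf21 went from 5.84 CPM ± 4.26 to 27.9 ± 7.69 (SD, n = 3 each), while Cyp4a32 fell by 1.97. Of 19 genes of lipid droplets and lipid uptake 7 rose, 6 fell and 6 did not pass, also adjusted over the list alone (median 0.32, camera adjusted p = 0.465, and adjusted p = 0.784 with an estimated correlation). Cidec, a droplet fusion protein, went from 25.4 CPM ± 0.826 to 105 ± 15.2, Apoa4 rose by 2.44, and the lipase inhibitor G0s2 fell by 3.26. Of 23 cholesterol genes 1 rose (Hmgcs1), 4 fell and 18 did not pass, also adjusted over the list alone (median 0.07, mean -0.01, camera adjusted p = 0.776, and adjusted p = 0.933 with an estimated correlation). The regulator Insig1 was among those that fell (-1.23).

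Glucose and amino acid genes fell together. Of 22 genes of gluconeogenesis and glucose handling 14 fell, none rose and 8 did not pass (18 fell adjusted over the list alone), with a median log2 fold change of -1.11 (camera adjusted p = 0.000147, and adjusted p = 0.391 with an estimated correlation). Fbp1, a committed enzyme of gluconeogenesis, went from 1051 CPM ± 251 to 294 ± 4.94 (SD, n = 3 each), and the glycogen genes Ppp1r3g, Pygl and Ppp1r3b fell by 3.54, 1.34 and 1.23. Of 31 genes of amino acid breakdown and the urea cycle 20 fell, 1 rose (Sdsl) and 10 did not pass (22 fell and 1 rose adjusted over the list alone), with a median of -1.14 (camera adjusted p = 4.42e-06, and adjusted p = 0.391 with an estimated correlation). The tyrosine enzyme Hpd fell by 2.09, the glycine methyltransferase Gnmt by 2.69, the urea cycle enzyme Asl by 1.66 and ornithine aminotransferase Oat by 3.31. Of 28 genes of xenobiotic metabolism 9 rose, 7 fell and 12 did not pass (11 rose and 8 fell adjusted over the list alone). Their median was -0.15 and their mean 1.00 (camera direction up, adjusted p = 0.148, 0.0497 without sham replicate 3, and adjusted p = 0.669 with an estimated correlation). The glutathione S-transferases Gstm1, Gstm2 and Gsta1 rose by 3.42, 3.83 and 7.33.

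Stress and injury genes rose. Of 23 genes of the oxidative stress response 15 rose, none fell and 8 did not pass, also adjusted over the list alone, with a median log2 fold change of 1.09 (camera adjusted p = 1.26e-05, and adjusted p = 0.391 with an estimated correlation). Sulfiredoxin Srxn1 rose by 3.31 (SE 0.29, edgeR adjusted p = 0.000308). Of 24 genes of endoplasmic reticulum stress 8 rose, 1 fell (Manf) and 15 did not pass (10 rose and 1 fell adjusted over the list alone; median 0.48, camera adjusted p = 0.0148, and adjusted p = 0.433 with an estimated correlation). Eif2ak3, which encodes the stress kinase PERK, rose by 2.02, and the stress pseudokinase Trib3 and the transcription factor Atf5 by 3.46 and 1.65. Of 17 genes of the p53 response and senescence 6 rose, 1 fell (Fas) and 10 did not pass, also adjusted over the list alone (median 0.64, camera adjusted p = 0.0172, and adjusted p = 0.511 with an estimated correlation). Cdkn1a (ENSMUSG00000023067, chromosome 17, 29090976 to 29100727 on GRCm38), the cell cycle inhibitor p21, went from 1.83 CPM ± 1.28 to 18.0 ± 7.29 (SE 0.53, edgeR adjusted p = 0.00296), and Mdm2 and Aen rose by 1.24 and 1.69. Of 19 Hippo and injured-hepatocyte genes 12 rose, 1 fell (Afp) and 6 did not pass, also adjusted over the list alone (median 1.29, camera adjusted p = 0.000147, and adjusted p = 0.391 with an estimated correlation), among them Klf6 (3.91), the Hippo regulator Ajuba (2.25) and Anxa5 (2.61). Klf6 was also a leading gene of cluster 13, whose identity stays open, and its value without that cluster is not given here. Without cluster 13 the list had a camera adjusted p of 0.000195.

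Cell division genes rose as well. Of 34 proliferation genes 19 rose, 1 fell (E2f8, from 14.6 to 3.69 CPM) and 14 did not pass (21 rose and 1 fell adjusted over the list alone), with a median log2 fold change of 1.24 (camera adjusted p = 8.83e-05, and adjusted p = 0.433 with an estimated correlation). The DNA polymerase subunit Pola1 rose by 1.15, and Diaph3 by 2.86, with a value of 0.76 under the first naming rule (edgeR adjusted p = 0.0772). Of 23 immediate early and heat shock genes 5 rose, 4 fell and 14 did not pass (6 rose and 4 fell adjusted over the list alone; median 0.22, camera adjusted p = 0.126, 0.0326 without SBR replicate 2, and adjusted p = 0.506 with an estimated correlation), and Myc and Klf4 rose by 3.57 and 2.90. Of 22 circadian clock genes 2 rose (Arntl and Npas2), 9 fell and 11 did not pass, also adjusted over the list alone (median -0.42, camera adjusted p = 0.0621, 0.0272 without sham replicate 2, 0.0321 without SBR replicate 1, and adjusted p = 0.433 with an estimated correlation). The clock output gene Dbp fell by 2.68, Bhlhe41 by 3.20 and Per3 by 1.30. Of 13 mitochondrially encoded transcripts 3 rose, none fell and 10 did not pass, also adjusted over the list alone (median 0.53, camera adjusted p = 0.0148, 0.07 without sham replicate 3, 0.137 without SBR replicate 2, and adjusted p = 0.607 with an estimated correlation), with mt-Nd1 at 1.04 and mt-Nd3 at 1.03.

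Transcripts of secreted acute phase proteins were lower. Of 30 acute phase genes 15 fell, 1 rose (Il1rn) and 14 did not pass, also adjusted over the list alone, with a median log2 fold change of -0.96 (camera adjusted p = 0.0064, and adjusted p = 0.433 with an estimated correlation). Saa4 fell by 4.69, the fibrinogen chains Fgg and Fgb by 1.57 and 1.23, and complement factor B, Cfb, by 1.06. Of 23 innate immune genes 4 rose, 4 fell and 15 did not pass, also adjusted over the list alone (median 0.28, camera adjusted p = 0.366, and adjusted p = 0.669 with an estimated correlation). The adhesion molecule Vcam1 and the endotoxin co-receptor Cd14 rose by 2.58 and 2.96, and the chemokine Cxcl1 fell by 3.27. Tlr4 (ENSMUSG00000039005, chromosome 4, 66827584 to 66930284 on GRCm38), the endotoxin receptor, had 124 counts in sham and 104 in SBR hepatocyte-like nuclei (log2 1.47, SE 0.39, edgeR adjusted p = 0.0189), with 1.29 (adjusted p = 0.0759) without sham replicate 2 and 1.52 (0.0505) without sham replicate 3. Of 30 interferon response genes 6 rose, 3 fell and 21 did not pass, also adjusted over the list alone (median 0.14, camera adjusted p = 0.385, and adjusted p = 0.857 with an estimated correlation), with Oas2 and Ifit2 up by 2.33 and 2.42 and the immunoproteasome subunit Psmb9 down by 1.86.

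Transcripts typical of other liver cells were higher in SBR hepatocyte-like nuclei. Of 30 fibrosis and matrix genes 11 rose, 1 fell (Fn1, -1.10, edgeR adjusted p = 0.0571 under the first naming rule) and 18 did not pass (13 rose and 1 fell adjusted over the list alone; median log2 1.04, camera adjusted p = 0.000147, and adjusted p = 0.433 with an estimated correlation). Ccn2, a matricellular protein, rose by 3.40. Col1a1 (ENSMUSG00000001506, chromosome 11, 94936224 to 94953042 on GRCm38), a fibrillar collagen made mainly by mesenchymal cells, had 35 counts in sham and 52 in SBR (log2 2.40, SE 0.55, edgeR adjusted p = 0.011, and 0.0634 with nuclei assigned by markers). Of 16 macrophage markers 12 rose, none fell and 4 did not pass, also adjusted over the list alone (median 1.51, camera adjusted p = 4.38e-05, and adjusted p = 0.391 with an estimated correlation), among them C1qb (2.26) and Vsig4 (2.02). Of 18 mesenchymal markers 10 rose, none fell and 8 did not pass (11 rose adjusted over the list alone; median 1.08, camera adjusted p = 9.79e-05, and adjusted p = 0.433 with an estimated correlation), and the stellate cell gene Reln went from 8.84 CPM ± 1.53 to 97.3 ± 24.9 (SD, n = 3 each). Of 9 cholangiocyte markers 4 rose, none fell and 5 did not pass, also adjusted over the list alone (median 0.60, camera adjusted p = 0.0148, and adjusted p = 0.391 with an estimated correlation), among them Glis3 (3.73) and Ddr1 (4.08). Of 18 endothelial markers 4 rose, none fell and 14 did not pass (2 rose adjusted over the list alone; median 0.36, camera adjusted p = 0.0148, 0.173 without SBR replicate 2, and adjusted p = 0.615 with an estimated correlation), among them Flt1 (1.97). The 3 others lost their calls in several settings: Pecam1 (1.34) without sham replicate 2 (edgeR adjusted p = 0.0531), F8 (0.64) without any sham replicate or SBR replicate 2 (0.059 to 0.0953) and Bmp2 (1.19) without any sham replicate or SBR replicate 2 or 3 (0.0682 to 0.115).

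The 5 other marker lists did not pass by camera in hepatocyte-like nuclei. Of 7 other myeloid markers 3 rose, 1 fell (Ccr9, -2.96) and 3 did not pass (median log2 0.79, camera adjusted p = 0.078, 0.0459 without SBR replicate 1, 0.0144 without SBR replicate 3, and adjusted p = 0.433 with an estimated correlation). Of 8 T and NK markers 1 rose (Tcf7, 1.44), 1 fell and 6 did not pass (median 0.93, camera adjusted p = 0.126, 0.0412 without SBR replicate 1, and adjusted p = 0.433 with an estimated correlation). Of 4 B and plasma markers none rose, 1 fell (Jchain, -2.46) and 3 did not pass (median 0.48, mean -0.15, camera adjusted p = 0.762, and adjusted p = 0.868 with an estimated correlation). Of 3 mesothelial markers 2 rose and 1 did not pass (median 1.81, camera adjusted p = 0.148, and adjusted p = 0.433 with an estimated correlation). Gpm6a (1.81) lost its call without sham replicate 2 or SBR replicate 3 (edgeR adjusted p = 0.071 and 0.082), and Muc16 (1.96) without sham replicate 2 or 3 or SBR replicate 2 or 3 (0.0945 to 0.134 by edgeR). Of 5 erythroid markers 3 rose, 1 fell (Alas2, -3.07) and 1 did not pass (median 1.77, mean 1.01, camera adjusted p = 0.344, and adjusted p = 0.669 with an estimated correlation). The counts of these 5 lists were the same adjusted over the list alone.

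**Figure D3:**
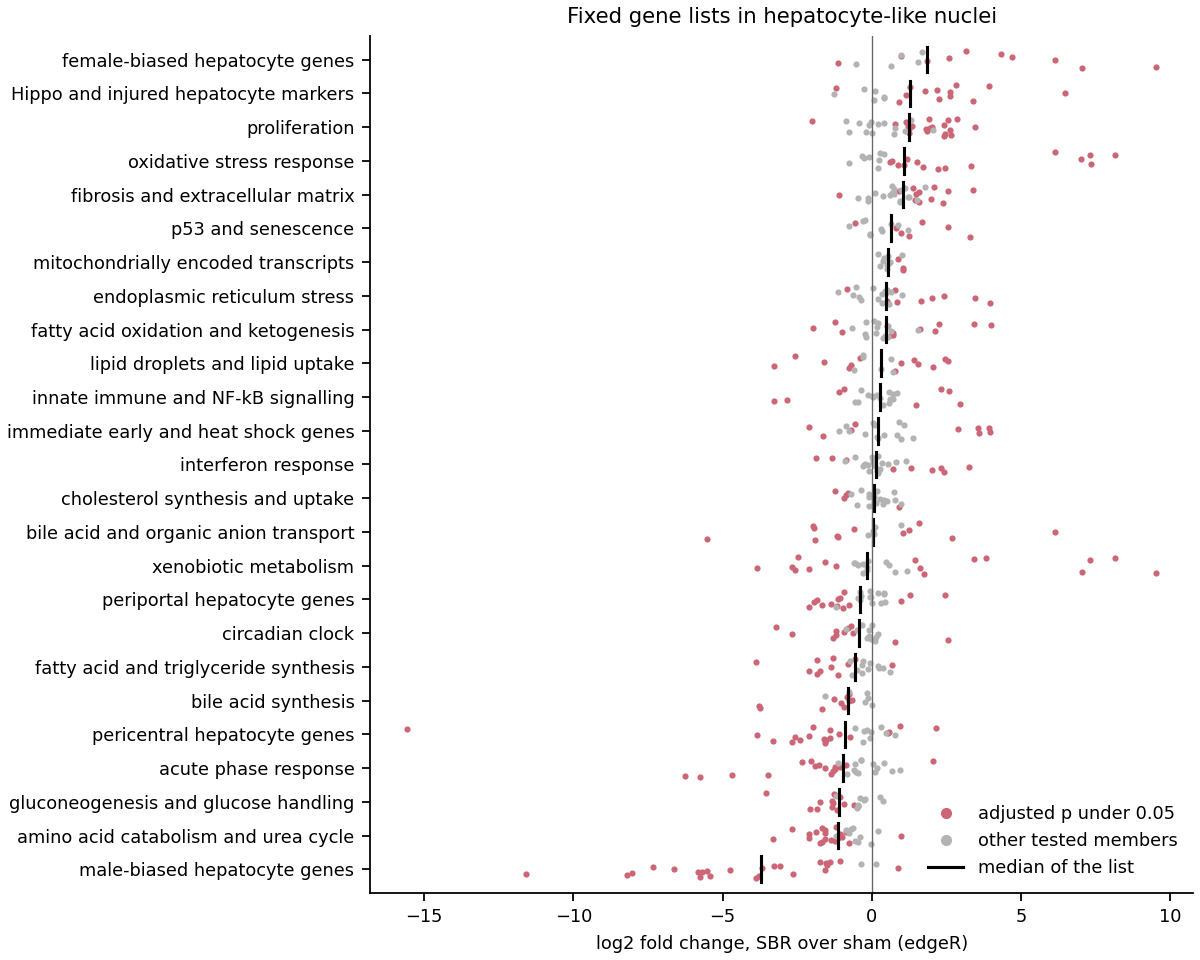
Median log2 fold change, SBR against sham, of each gene list in hepatocyte-like nuclei, with its tested members as points. The marker lists are not drawn. The male-biased list lay lowest at -3.72, and the female-biased list had a median of 1.85.

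Pericentral genes were lower by camera, and the call was lost without cluster 13. Hepatocytes near the central vein and near the portal vein carry different enzymes. Of 28 pericentral genes 15 fell, 4 rose (among them Znrf3, Slc1a4 and Csad) and 9 did not pass (15 fell and 5 rose adjusted over the list alone), with a median log2 fold change of -0.91 (camera adjusted p = 0.023, and adjusted p = 0.433 with an estimated correlation), also with Mup17 at its bound. Cyp2e1, an ethanol-metabolizing P450, went from 712 CPM ± 249 to 112 ± 33.8 (SD, n = 3 each), and the glutamate carrier Slc1a2 fell by 2.40. Without cluster 13 the camera adjusted p was 0.0632. The periportal list did not pass. Of 28 periportal genes 11 fell, 3 rose (Sdsl, Apoa4 and Cdh1) and 14 did not pass (14 fell and 3 rose adjusted over the list alone; median -0.39, camera adjusted p = 0.078, 0.336 without cluster 13, and adjusted p = 0.391 with an estimated correlation).

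The third comparison asked whether the response differed along the lobule. In sham, the flavin monooxygenase Fmo2 and the retinol dehydrogenase Rdh16 were higher in the most pericentral nuclei, and in SBR both were higher in the most periportal nuclei. Fmo2 averaged 40.7 CPM in central and 4.88 CPM in portal nuclei of sham, and 62.9 and 198 CPM in SBR. Rdh16 averaged 293 and 71.4 CPM in sham and 23.8 and 105 CPM in SBR. Nnmt, a nicotinamide methyltransferase, averaged 360 and 346 CPM in sham, and 9.31 and 109 CPM in SBR. The phosphatase Dusp10 and the choline kinase Chka were higher in central nuclei of SBR alone, with 135 and 17.8 CPM for Dusp10 and 1241 and 340 CPM for Chka, against 14.3 and 14.6 CPM and 153 and 193 CPM in sham.

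The change in the portal to central log2 ratio was 4.72 for Fmo2 (SE 0.16, edgeR adjusted p = 1.04e-07), 3.60 for Nnmt, -2.96 for Dusp10, 4.27 for Rdh16 and -2.21 for Chka. The same direction of change held in each of 3 SBR samples against each of 3 sham samples. In all, 5279 of 15588 genes passed this interaction (2829 higher and 2450 lower at the portal end in SBR relative to sham, edgeR's quasi-likelihood test, 6751 at an unadjusted p below 0.05). For 3331 of them the estimated ratio had opposite signs in the groups, whether or not it differed from 0 in each. The portal to central difference itself passed for 3568 genes in sham and 6529 in SBR. The central and portal ends were the outer parts, when nuclei are ranked and split into 3, of a score from the pericentral and periportal lists, a range and not a cell type, with 1274 to 3883 nuclei each. Within 0.05 of the boundary lay 247 to 606 central and 381 to 1481 portal nuclei. The pericentral list separated the ends less in SBR (median log2 ratio -1.09, -1.22 and -0.66) than in sham (-3.76, -3.54 and -3.55). The periportal list separated them more in SBR (2.22, 2.24 and 2.43) than in sham (1.91, 1.91 and 1.88). The central end of SBR held 38.78%, 28.83% and 61.77% cluster 13 nuclei and that of sham at most 0.14%, and without that cluster 3169 genes passed.

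**Figure D4:**
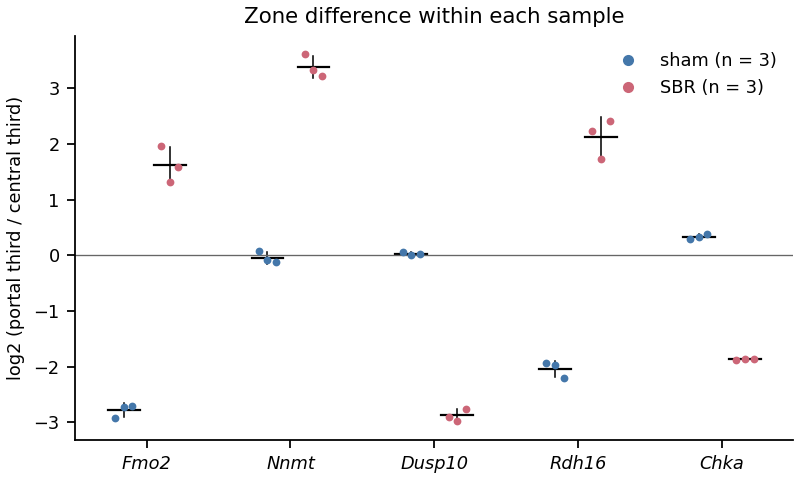
Log2 ratio of portal to central counts in hepatocyte-like nuclei for the 5 genes with the lowest interaction p, 1 point per sample. For Fmo2 the sham samples lay between -2.93 and -2.70 and the SBR samples between 1.33 and 1.96.

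The remaining comparisons asked how the other cell classes differed. Counts summed over endothelial-like nuclei of SBR livers held more oxidative stress and immediate early transcripts. They held fewer transcripts of the male-biased list, which was written for hepatocytes. Of 12199 genes 1205 were higher and 1191 lower (edgeR's quasi-likelihood test), and 4853 (39.8%) did not overlap between the groups, where chance gives 10%. Of 22 oxidative stress genes 13 rose and none fell (median log2 0.75, camera adjusted p = 1.57e-07, and adjusted p = 0.039 with an estimated correlation), and of 24 male-biased genes 15 fell and 1 rose (median -2.52, camera adjusted p = 1.26e-11, and adjusted p = 0.039 with an estimated correlation). Of 20 immediate early and heat shock genes 11 rose and none fell (camera adjusted p = 1.93e-06, and adjusted p = 0.039 with an estimated correlation), and of 15 macrophage markers 12 rose and none fell (camera adjusted p = 1.57e-07, and adjusted p = 0.039 with an estimated correlation). Of 14 mesenchymal markers 5 rose and none fell (median 1.07, camera adjusted p = 0.00019, and adjusted p = 0.46 with an estimated correlation), and of 14 hepatocyte markers 4 rose and 3 fell (median -0.06, camera adjusted p = 0.92, and adjusted p = 0.983 with an estimated correlation). Runx1, a transcription factor of blood-forming endothelium, rose by 3.36 and Srxn1 went from 2.75 CPM ± 1.37 to 42.1 ± 4.05 (SD, n = 3 each). Apoa4, Gstm1 and Krt8 rose by 3.79, 3.68 and 3.52, and Mup17 was at least 197-fold lower (1020 counts against 0). The phosphatase Ptprr and the epithelial gene Plet1 fell by 2.86 and 2.55, and Rec114 by 2.40. Most sham nuclei of the class lay in cluster 8 (90.6%) and most SBR nuclei in cluster 11 (88.7%). Without sham replicate 1, sham replicate 2 or SBR replicate 3, 1573, 1469 and 1465 genes passed. Pard3bos1 fell by 2.61, an antisense gene whose reads cannot be told from those of its partner unless the counting used strand. Of these 10 genes all but Ptprr, which was not tested there, passed in the same direction in hepatocyte-like nuclei. RNA of other cells was not estimated for this class or the others below. Hepatocyte RNA in these sums and expression by the class itself therefore cannot be told apart, above all for the male-biased genes.

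Mesenchymal-like nuclei of SBR livers carried more Thbs1, an activator of TGF-beta, more of the guidance cue Slit3 and more collagen Col1a1. Slit3 rose by 2.73 and Thbs1 by 2.52 on the log2 scale, and Col1a1, chosen in this class after its values had been seen, by 1.36 (edgeR adjusted p = 0.00108). The list of fibrosis and matrix genes did not pass: of 32 genes 10 rose, 4 fell and 18 did not pass (median 0.12, camera adjusted p = 0.082, and adjusted p = 0.525 with an estimated correlation). Of 11869 genes 1242 were higher and 1251 lower (edgeR's quasi-likelihood test), and 4770 (40.2%) did not overlap, where chance gives 10%. Apoa4 and Gstm1 rose by 3.77 and 2.56. Hba-a1, a haemoglobin chain, rose by 2.60, with a value of 1.86 (edgeR adjusted p = 0.102) under the stricter filter. The clock gene Npas2 fell by 2.42, while it rose by 2.54 in hepatocyte-like nuclei, a difference between classes that was not tested. Kcnrg fell by 2.12, and the antisense genes Sox5os3 and Far1os by 2.40 and 2.19. Adap2os had a value of -2.64 (edgeR adjusted p = 0.021, and 0.0648 to 0.0994 without any sham replicate or SBR replicate 3). Without sham replicate 1, sham replicate 2 or SBR replicate 3, 1655, 1500 and 1482 genes passed. Slit3, Col1a1, Apoa4, Gstm1, Hba-a1, Kcnrg and Adap2os passed in the same direction in hepatocyte-like nuclei, where Thbs1 and Far1os were not tested and Sox5os3 did not pass. Cluster 14 held 96.6% of sham and cluster 10 97.4% of SBR nuclei of the class.

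Macrophage-like nuclei of SBR livers carried more Gpnmb and Mmp12. Gpnmb, a lysosomal glycoprotein, had 1 count in sham and 507 in SBR, a ratio of 261 (95% counting interval 46.6 to 10300; edgeR adjusted p = 0.00105), and the elastase Mmp12 rose by 3.91 (SE 0.47, edgeR adjusted p = 0.00224). Of 10779 genes 584 were higher and 655 lower (edgeR's quasi-likelihood test), and 3612 (33.5%) did not overlap, where chance gives 10%. Of 23 proliferation genes 9 fell and none rose (median log2 -1.28, camera adjusted p = 4.93e-06, and adjusted p = 0.447 with an estimated correlation). Cluster 6 held 90.2% of sham and 65.2% of SBR nuclei of the class, cluster 16 held 4.1% and 33.6%, with 931 nuclei from SBR replicate 2, and cluster 28, a cycling one, 5.6% and 1.2%. Cenpf (-2.85), Kif4 (-2.98) and Nusap1 (-2.67) each lost the call without sham replicate 2, at -1.80, -2.03 and -2.16 (edgeR adjusted p = 0.0745, 0.101 and 0.0948), as did the adhesion gene Sdk1 (-2.92, then -1.81 at 0.0841). They lost it too without SBR replicate 2 (0.0548, 0.0679, 0.0567 and 0.0604 in the same order by edgeR). Without SBR replicate 1 the values were 0.0838 for Cenpf, 0.0909 for Kif4 and 0.0937 for Sdk1, without SBR replicate 3 they were 0.0693 for Cenpf and 0.115 for Sdk1, and without sham replicate 1 the value was 0.0585 for Nusap1 (edgeR adjusted p throughout). With doublets kept they were 0.0943 for Kif4, 0.0566 for Cenpf and 0.0592 for Nusap1, and with no count filter 0.219 for Sdk1 (edgeR adjusted p). Of 10 Hippo and injury genes 5 rose and none fell (median 1.09, camera adjusted p = 3.58e-06, and adjusted p = 0.0928 with an estimated correlation). Chst11 rose by 3.70 (edgeR adjusted p = 0.101 with no filter on low counts) and Apoa4 by 4.01, and Dscaml1 fell by 3.54. The proton pump subunit Atp6v0d2 rose by 3.42 (edgeR adjusted p = 0.0188), and lost the call without sham replicate 3 and without SBR replicate 3 (edgeR adjusted p = 0.0687 and 0.0713). Gpnmb, Mmp12, Chst11, Apoa4 and Atp6v0d2 passed in the same direction in hepatocyte-like nuclei. Against 1239 genes in all, 677 passed without sham replicate 1, 551 without sham replicate 2 and 451 without SBR replicate 3.

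Other myeloid-like nuclei also carried more Mmp12, with 0 counts in sham and 144 in SBR, at least 13.3-fold higher (edgeR adjusted p = 0.0031). Fblim1 had 1 and 125 counts (ratio 34.5, 95% counting interval 6.08 to 1370), and Atp6v0d2 had 1 and 143 (ratio 39.5, 6.97 to 1570; edgeR adjusted p = 0.0522 without sham replicate 2). The transcription factor St18 rose by 4.77 and Apoa4 by 4.12 on the log2 scale. The lectin Clec1a, the antigen presentation gene H2-Ob, Rgs7bp and Olfr164 fell (-3.35, -3.20, -2.76 and -5.15), and Mup17 was at least 91.8-fold lower (76 counts against 0). Of 6316 genes 536 were higher and 518 lower (edgeR's quasi-likelihood test), and 2190 (34.7%) did not overlap, where chance gives 10%. Without SBR replicate 3, 644 genes passed. Mmp12, Fblim1, Atp6v0d2, St18, Apoa4 and Mup17 passed in the same direction in hepatocyte-like nuclei. Of the sham nuclei 66.1% and of the SBR nuclei 89.0% lay in cluster 15.

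The changes named in T and NK-like nuclei were largely in genes that also changed in hepatocyte-like nuclei. Krt8, Gstm1 and Apoa4 rose by 4.36, 3.93 and 3.20 on the log2 scale, as they did in hepatocyte-like nuclei. Mup11 was at least 63.3-fold (172 counts against 0), Mup7 at least 32.8-fold and Mup17 at least 31.3-fold lower, all against 3 counts over the group. Serpina1e had 222 and 3 counts (ratio 81.7, 95% counting interval 27.6 to 399; edgeR adjusted p = 0.0577 without SBR replicate 3) and Mup3 571 and 22 (log2 -4.64, then -5.05 with an edgeR adjusted p of 0.0963 without SBR replicate 3). Slc25a39 rose by 2.26, with a value of 1.12 (edgeR adjusted p = 0.0513) with doublets kept. Cenpp rose by 2.51 (edgeR adjusted p = 0.0237, and 0.059 to 0.132 without SBR replicate 1 or 2 or sham replicate 1 or 3), with 0.79 (edgeR adjusted p = 0.461) with doublets kept and an adjusted p of 0.0599 by DESeq2. Of 5039 genes 134 were higher and 173 lower (edgeR's quasi-likelihood test), and 1189 (23.6%) did not overlap, where chance gives 10%. Without SBR replicate 3, 163 genes passed.

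Cholangiocyte-like nuclei carried more of the imprinted gene Peg3 (log2 2.28, edgeR adjusted p = 1.96e-05), of Megf6 (1.84) and of Gstm1 (2.39). Their sums held fewer transcripts of the male-biased list, which was written for hepatocytes and may stem from hepatocyte RNA. Of 13 male-biased genes 7 fell and none rose (median -2.51, camera adjusted p = 1.12e-13, and adjusted p = 0.0295 with an estimated correlation). Of 5076 genes 29 were higher and 103 lower (edgeR's quasi-likelihood test), and 1067 (21%) did not overlap, where chance gives 10%. Without SBR replicate 3, 59 genes passed, and without sham replicate 1, 83. The ribosomal protein Rpsa had 1.91, and 1.72 (edgeR adjusted p = 0.0638) without SBR replicate 1. Ccn2 had 1.93, with edgeR adjusted p values of 0.0587 to 0.284 without SBR replicate 2 or 3 or sham replicate 1 or 2, and 0.0771 by DESeq2. The calls of Sorbs2os (-2.70), Sox5os4 (-2.11) and Dalrd3 (-2.10) were lost without SBR replicate 3, with edgeR adjusted p values of 0.0565, 0.0885 and 0.168. Dalrd3 lost it too without SBR replicate 2, sham replicate 1 or sham replicate 3 (0.0692, 0.0676 and 0.193 by edgeR) and by DESeq2 (adjusted p = 0.117). Adamts16 (-2.44) lost it without SBR replicate 1 (edgeR adjusted p = 0.0722) and Kcnrg (-2.68) without sham replicate 1 (0.0542). Peg3, Gstm1, Ccn2, Rpsa, Sorbs2os, Kcnrg and Dalrd3 passed in the same direction in hepatocyte-like nuclei, where the male-biased list also fell. B and plasma-like nuclei were not tested, since SBR replicate 2 held 9 of them.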

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

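The tests of sex, of depth per nucleus, of dilution by other cells' RNA, of hepatocyte recovery, of SBR replicate 2 and of other splits were chosen after the results were seen. Those of thinned libraries on shares and of other cells' RNA on the genes that rose were written before.

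The difference between the portal and the central end of the hepatocyte ranking differed with surgery for 5279 genes, by a test of the interaction itself. The change in the portal to central log2 ratio was 4.72 for Fmo2, 3.60 for Nnmt, -2.96 for Dusp10, 4.27 for Rdh16 and -2.21 for Chka. The central end of SBR held 28.83 to 61.77% cluster 13 nuclei and that of sham at most 0.14%, and without that cluster 3169 genes passed. Another mix of nuclei at the central end and a response that depends on the place in the lobule were not separated by this test.

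Male-biased genes fell and female-biased genes rose in SBR hepatocyte-like nuclei of male mice. Female tissue would lack Y-linked transcripts, but the median log2 fold change of 4 Y-linked genes was 0.07, which argues against it. With nuclei thinned to 1000 UMIs the male-biased median was -3.67, but random thinning leaves each gene's expected share of UMIs unchanged. This could not decide whether lower depth played a part. Dilution by other cells' RNA would lower hepatocyte markers alike, yet the male-biased median lay at -3.45 relative to theirs. Those markers had also named the clusters, which limits this comparison. A response of the resected animals' hepatocytes may be the source, as a hypothesis found on the same data, and effects that come with lower depth stay open.

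Macrophage-like and other myeloid-like shares were larger in SBR. Poor recovery of hepatocyte nuclei would raise all other classes alike, but outside the hepatocyte class the macrophage-like share still differed by 13.01 percentage points, and by 13.07 with unnamed nuclei left out as well, without overlap, and the endothelial-like share was lower (25.2% against 38.79%). Lower depth would act through which nuclei pass the filter, and with every library thinned to the median UMIs per nucleus of the shallowest, which leaves the spread of depth unmatched, the difference was 9.34 points, again without overlap. Which nuclei survived release and sorting was not measured, so a gain of macrophages in the liver stays a hypothesis that these tests leave open, with 3 samples per group.

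With nuclei thinned to 1000 UMIs, 81.6% of the 5145 called hepatocyte genes still tested, out of 6882 called, kept their direction and call. Random thinning leaves each gene's expected share of UMIs unchanged, so this could not decide whether lower depth played a part. Without SBR replicate 2 alone 6599 genes were called. RNA of other cells, estimated at 1.55 to 1.9% of sham and 3.99 to 5.47% of SBR hepatocyte-like UMIs, would lower all transcripts that other cells lack alike. The genes that fell had a median decrease of 1.51 log2 units. Of 14 hepatocyte markers 9 fell by less than that or, for C3, did not fall, in each case by over 2 standard errors. This argues against dilution as the whole cause and leaves it open for small decreases. The same markers had named the clusters, so nuclei with weak markers may have been left out beforehand. Of the genes that rose 45.8% lay in every SBR sample above the highest level that RNA of other cells could bring. For the other genes that rose, such RNA and expression in hepatocytes cannot be told apart. The bound rests on a share that was only estimated, from these same libraries, and the test did not decide for the whole set. With 10 splits of the 6 samples too few for a share under 0.05, the real split called 6882 hepatocyte genes and the highest other split 0, with 1 split of the 10 as large as the real one.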

How the results depend on the processing

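Added after the data were seen were the 3 naming rules, leaving out cluster 13, cluster 5 or 8 genes such as Gm42418, leaving unnamed nuclei out of the shares outside hepatocytes, and leaving out samples for depth and for the lists of other classes. No paired analysis was possible because the labels give no replicate numbers, and accession order pairs nothing. Of 3522 values of 203 named results under alternatives, 3252 kept direction and call, 242 kept the direction and lost the call, and 28 reversed. Leaving out each sample gave 80 lost calls in 1215 values over 30 results. The cause was not tested for any of the differences below except the reversals.

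All 28 reversals came with the other-cell marker share as a covariate. That share does not overlap between the groups, so group and covariate are nearly the same term: the median standard error of the 6882 called genes went from 0.29 to 1.90 and their median absolute log2 fold change from 1.34 to 1.15, 71.1% kept their sign, and 689 genes had an unadjusted p below 0.05, against 8552. It called 5 hepatocyte genes. Mup9, Mup10, Mup11 and Elovl3 kept their calls. The log2 values that reversed were Saa2 8.88, Tm7sf2 1.44, Acly 2.07, Acot2 -0.93, Fgf21 -1.17, Fbp1 0.30, Oat 1.42, Trib3 -0.16, Atf3 -4.45, Fgg 0.22, Cfb 0.30, Fgb 1.15, Cxcl1 4.33, Cdkn1a -0.23, Eda2r -2.78, Cyp2a4 -12.97, Per3 0.21, Flt1 -0.60, Pecam1 -0.16, Bmp2 -1.29, Rgs5 -0.73, Ccr2 -0.14, Flt3 -1.91, Anxa4 -0.77, Gpm6a -4.78, Hba-a1 -0.26, Cyp7a1 1.34 and Tlr4 -1.65.

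Hepatocyte counts ran from 4709 to 6599 without single samples, against 6882, and were 4371 with thinned nuclei and 4406 under the first naming rule. Under the estimated correlation 0 lists passed in hepatocytes and 5 in other classes, against 19 and 66. Without single samples 18 to 22 and 61 to 73 passed. For classes tested above their hepatocyte level the counts were 1488 endothelial, 1306 mesenchymal, 765 macrophage and 173 T and NK genes. With doublets kept they were 3900 mesenchymal, 2798 macrophage, 843 T and NK and 337 cholangiocyte genes. With no count filter 2274 macrophage and 352 cholangiocyte genes passed, and by DESeq2 129 T and NK and 84 cholangiocyte genes. Without single samples the ranges were 1465 to 2317 endothelial, 1482 to 2556 mesenchymal, 451 to 1173 macrophage, 163 to 303 T and NK, 59 to 172 cholangiocyte and 644 to 962 other myeloid genes. The lobule interaction called 3169 genes without cluster 13 and 4038 to 5029 without single samples.

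Under the stricter filter 2 classes were without overlap in place of 5, and the share differences were -2.406 points for endothelial-like and -0.05433 for T and NK-like nuclei. Without single samples they ran from -0.7407 to 2.995 for endothelial-like and from -0.1465 to 0.01948 for B and plasma-like nuclei. By edgeR on nuclei counts the log2 ratios were -0.42 hepatocyte-like, 0.66 mesenchymal-like, 1.65 macrophage-like and 2.74 other myeloid-like. Sub-clusters without overlap numbered 10 with differing genes left in and 6 to 10 without single samples. Not run were the stricter filter for T and NK-like (6 nuclei in SBR replicate 2) and cholangiocyte-like nuclei (11), and all tests of B and plasma-like nuclei (9). Median depth per nucleus ranged from 2031 to 8851 UMIs.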

Other observations

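The shares outside the hepatocyte class, the test of growth hormone signalling and those of other splits were chosen after the results were seen. Among nuclei outside the hepatocyte class, unnamed ones included, macrophage-like nuclei made up 28.42% ± 2.21 (SD, n = 3) in SBR and 15.41% ± 0.529 (SD, n = 3) in sham, and other myeloid-like nuclei 9.723% and 2.649%. Endothelial-like nuclei made up 25.2% ± 3.38 and 38.79% ± 3.98, and B and plasma-like nuclei 0.4973% and 1.119%. Each of these 4 classes was without overlap (two-sided exact permutation p = 0.1, the smallest the design allows). Mesenchymal-like nuclei made up 24.64% and 25.96% (p = 0.7), cholangiocyte-like 1.776% and 1.779% (p = 1.0) and T and NK-like 3.263% and 3.371% (p = 0.9, exact permutation). Unnamed nuclei made up 6.477% and 10.92%, also without overlap, and cluster 22 among them carried hepatocyte markers (182, 186 and 106 nuclei in the sham samples, 1, 0 and 2 in SBR). With unnamed nuclei left out as well, the same 4 classes stayed without overlap: macrophage-like 30.39% in SBR and 17.31% in sham, other myeloid-like 10.4% and 2.979%, endothelial-like 26.94% and 43.49%, and B and plasma-like 0.532% and 1.256%.

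Other hepatocyte genes of the oxidative stress list, chosen after their values were seen, included Slc7a11, the cystine carrier, at a log2 fold change of 7.34, the quinone reductase Nqo1 at 2.21 and Gclc, of glutathione synthesis, at 2.46 (edgeR adjusted p = 0.000355, 0.00456 and 0.00566). Slc7a11 was also a leading gene of cluster 13, nearly absent from sham and of open identity. Its value without that cluster is not given here, so a different mix of nuclei may carry part of its rise. Of the cell division genes Top2a was at 2.65 and Mki67 at 2.42 (edgeR adjusted p = 0.00654 and 0.0192). Albumin and the urea cycle gene Cps1 did not pass, at -0.23 and -0.02 (edgeR adjusted p = 0.414 and 0.927).

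Lower growth hormone signalling was considered as a candidate explanation of the sex-biased genes, since the male pattern of the hormone sustains them. The median log2 fold change of 5 genes of that pathway was -0.36, between the bounds of -0.5 and 0 set for the test, so it decides nothing. Igf1, Igfals, Socs2 and Ghr are also members of the male-biased list, so the test was not independent of the pattern to be explained. Ghr and Igfals fell by 1.53 and 1.41, while Igf1, Socs2 and Cish did not pass, at -0.36, 0.13 and 1.01.

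The other comparisons were refitted over the same 10 splits of the samples, too few for a share under 0.05. The real split called 2396 endothelial, 2493 mesenchymal, 1239 macrophage, 307 T and NK, 132 cholangiocyte and 1054 other myeloid genes and 5279 genes of the lobule interaction, and the highest other split called 0 in each, so that 1 split reached the real count.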
